A study of Caenorhabditis elegans with 27 samples.

How the data were processed

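The values were log2 expression per probe set that the authors deposited, made with GCRMA according to their processing notes, which name no version. GCRMA corrects the background, normalizes and summarises the probes of each set. The deposited values of the 3 experiments had separate distributions, with 75th percentiles of 7.46 to 7.53 for HF at 3 days, 7.36 to 7.43 for HF at 11 days and 9.29 to 9.39 for HF-HQ, so that the experiments appear to have been normalized apart. No further normalization was applied in the first place. The log2 changes within an experiment compared arrays of like distributions, but the filter and the variance estimate drew on all 27 arrays. Comparisons between experiments were also made after quantile normalization of all 27 arrays.

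According to the labels, worms were kept at 15 °C, first-stage larvae were filtered through 10 µm mesh, and 15000 larvae per plate were cultivated at 25 °C to the age of 3 or 11 days. Fresh humic substance was given repeatedly with the food. RNA of whole worms had an integrity number of 9 or 10, and 200 ng were amplified. The replicate numbers were not used as pairs, because deviations of arrays with the same number from their group means were not alike (3 of 27 correlations were over 0.1 and 16 were negative).

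Of 22625 probe sets 77 array controls were left out, and the remaining 22548 were tested where log2 was over 5 in at least 3 of 27 arrays, which left 11102. Of these 10533 matched 1 gene symbol, 378 several and 191 none, and they stood for 8363 genes. Members of several families, such as the MSP, ssp, collagen and yolk protein genes, have near-identical copies, and probe sets of these share signal, so that their counts are not counts of independent genes. A model with 1 mean per group over all arrays was fitted with limma 3.58.1 in R 4.3.3, with its moderated variance, and 15 contrasts were tested with a 2-sided test. Adjusted p values are those of Benjamini and Hochberg within a contrast, and a probe set was called where this was under 0.05. Figures were drawn in Python 3.11.15 with matplotlib.

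Before the data were examined, 37 gene lists were written down from general knowledge of the worm. They covered lysozymes, C-type lectin-like proteins, antimicrobial peptides, cytochrome P450, UDP-glucuronosyltransferases, glutathione S-transferases, short-chain dehydrogenases, ABC transporters, nuclear hormone receptors, antioxidant defence, metal response, heat shock, the unfolded protein response, autophagy, DAF-16 regulated genes, insulin-like peptides, TGF-beta and dauer genes, fatty acid metabolism, the glyoxylate cycle and gluconeogenesis, oxidative phosphorylation, ribosomal proteins, histones, the cell cycle, oocyte and germ line, eggshell, MSP, other sperm genes, yolk proteins, embryonic genes, collagens, moulting and hedgehog-like proteins, transthyretin-related proteins, chitinases, F-box proteins, body wall muscle, neurons and intestine. Each gene stood once, with its probe set of the highest mean. For 36 lists with at least 5 tested genes, camera of limma compared the list with the other genes, with a preset correlation of 0.01 and with an estimated one, and fry tested the list by itself. These p values were adjusted together over 216 tests of the 6 treatments, 36 of age and 72 of the difference between preparations. The other contrasts had no such test.

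The rule for naming genes was also set before the data were examined. Per comparison of treated with untreated worms, and for age, these were the 6 largest rises and falls among called probe sets of 1 symbol whose treated arrays all lay above or below all controls, which chance gives for 10% of probe sets. For the 6 lists with the smallest camera p that held a called gene, up to 3 called genes with the largest change were added, and 1 gene that was not called where less than 50% of the list was called. The yolk protein genes were always reported. For differences between doses, ages and preparations these were the 5 largest each way. A selection of these is printed.

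The procedure was tested on simulated data with true changes set in the comparison at 3 days with 2.0 mM HF. Of 100 probe sets with a true change of 0.5 it recovered 79, and of 100 with a change of 1 it recovered 100, with 12 false calls among 191. Of 36 lists camera found the raised one and called no other. The simulated genes varied independently, so this does not test lists of correlated genes. The simulation also does not test comparisons with a group whose arrays spread more widely, such as that with 0.2 mM HF-HQ.

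The alternatives tried were no filter, a stricter filter at log2 7, centring of the arrays on their medians, quantile normalization over all arrays, a variance trend with intensity, a replicate block, a fit of only the arrays of each comparison, pooled controls of both 3-day experiments, and leaving out each array in turn. For the lists these were an estimated correlation, fry, the mean over all probe sets of a gene, a replicate block and leaving out replicates.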

Results

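The data were Affymetrix expression arrays of whole Caenorhabditis elegans of strain GE24, which carries the temperature-sensitive allele pha-1(e2123). The worms had been kept with HuminFeed (HF), a humic substance preparation, or with HuminFeed-Hydroquinone (HF-HQ), at 0, 0.2 or 2.0 mM dissolved organic carbon. Worms with HF were harvested at an age of 3 or 11 days and worms with HF-HQ at 3 days. Each of these 3 experiments had its own control, which made 9 groups of 3 arrays and 27 arrays. The design calls the worms adults, although the age tag of all 27 arrays reads fourth-stage larvae. Between 8818 and 10491 of 22548 probe sets lay over log2 5 per array, and correlations within groups over all probe sets were 0.997 to 0.999. Over the tested probe sets the lowest was 0.987, between arrays 1 and 2 with 0.2 mM HF-HQ. Each condition was cultivated in triplicate, but the labels do not say whether the triplicates were independent populations, so the p values below are tied to a spread between arrays whose source is not stated (median SD 0.0978 at 3 days with HF, 0.0952 at 11 days and 0.119 with HF-HQ). The small number of arrays limits precision, and the size of very large changes depends on how GCRMA treats values near the floor of its scale.

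The first comparison asked how 3-day-old worms kept with 0.2 mM HF differed from untreated worms of the same experiment. Transcripts of egg production and cell division fell. Of 44 tested oocyte and germ line genes 39 fell and 5 did not pass the test, or 1 rose and 40 fell adjusted over the list alone (median log2 change -0.45, camera adjusted p = 6.7e-08). In this list egg-3, which is needed for egg activation, fell by 0.91 ± 0.13 (log2 change ± SE, n = 3 per group) and csr-1, an Argonaute gene, fell by 0.82 ± 0.07. Of 49 genes of DNA replication and the cell cycle 41 fell, 1 rose and 7 did not pass, with the same counts adjusted over the list alone (median -0.45, camera adjusted p = 1.6e-09), and cya-1, which encodes cyclin A, fell by 1.07 ± 0.18. Genes of the gut and of its contact with bacteria rose instead. Of 28 intestinal genes 23 rose and 5 did not pass, or 24 rose adjusted over the list alone (median 0.37, camera adjusted p = 1.9e-07), with 0.90 ± 0.10 for the intermediate filament gene ifc-2. Of 51 genes of C-type lectin-like proteins 34 rose, 4 fell and 13 did not pass, with the same counts adjusted over the list alone (median 0.46, camera adjusted p = 5.8e-07), with 1.76 ± 0.11 for clec-67.

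Major sperm protein (MSP) genes, whose products form the cytoskeleton of the crawling sperm, rose at this dose in 31 of 33 cases and 2 did not pass, or 33 rose adjusted over the list alone (median 0.54, camera adjusted p = 1.2e-08). The list called MSP genes here and below also holds genes of the ssp and sss families. Camera gave adjusted p = 0.196 with an estimated correlation. Of 77 cuticle collagen genes 45 rose, 2 fell and 30 did not pass, with the same counts adjusted over the list alone (median 0.20, camera adjusted p = 5.9e-06). The list had adjusted p = 0.166 with an estimated correlation. Among single genes the largest rises were those of the F-box gene fbxa-163 (2.48 ± 0.09), of clc-32 (2.34 ± 0.16), of the invertebrate-type lysozyme gene ilys-3 (from 5.59 ± 0.16 to 7.81 ± 0.07, SD, n = 3, adjusted p = 4.9e-13) and of the glutathione S-transferase gene gst-24 (from 7.22 ± 0.11 to 9.43 ± 0.06). The largest fall was that of nspe-1 of a nematode-specific peptide family, from 8.38 ± 0.08 to 4.64 ± 0.03 (SD, n = 3, adjusted p = 5.4e-15). Also nspe-7 fell by 2.83 ± 0.15, and C10C5.3 and F35A5.2 fell by 2.38 and 1.91. In each of these genes all 3 treated arrays lay beyond all 3 control arrays. Of the yolk protein genes vit-1 fell by 0.29 ± 0.09 (adjusted p = 0.011, or 0.0034 to 0.0766 over 13 alternatives, with the call lost without control 2, without treated array 3 and after centring), while vit-2, vit-4, vit-5 and vit-6 did not pass (0.01, -0.03, -0.12 and 0.01). In all, limma called 6537 of 11102 probe sets, 2887 up and 3650 down, of which 157 and 98 changed at least 2-fold, and this balance turned to 3528 up and 2982 down with median-centred arrays. The 5′ minus 3′ signal of the ubiquitin control probe sets was -3.10 ± 0.04 in these worms and -2.95 ± 0.03 in their controls (SD, n = 3).

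**Figure D1:**
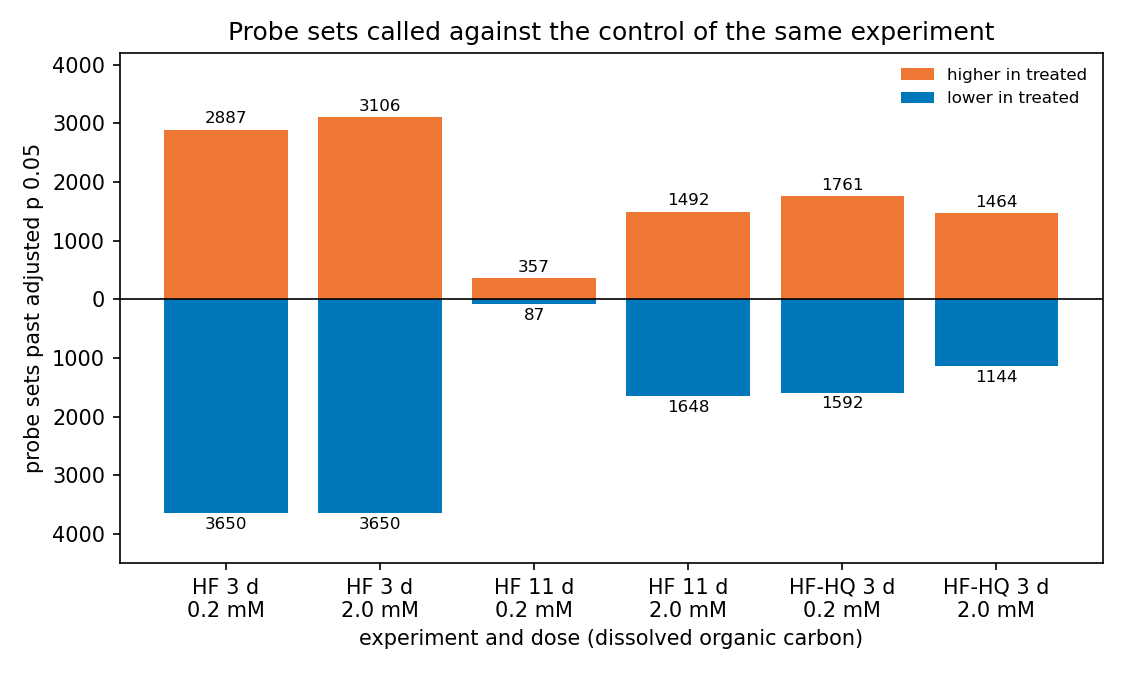
Number of called probe sets (vertical axis, counts), higher in treated worms upwards and lower downwards, in the 6 comparisons of treated with untreated worms (horizontal axis, experiment and dose), n = 3 arrays per group. The counts ran from 444 at 11 days with 0.2 mM HF to 6756 at 3 days with 2.0 mM HF.

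The second comparison asked how 3-day-old worms kept with 2.0 mM HF differed from the same untreated worms. Transcripts of sperm fell. Of 33 MSP genes 32 fell and 1 did not pass, or 1 rose and 32 fell adjusted over the list alone (median -1.13, camera adjusted p = 2.6e-12). It had adjusted p = 0.129 with an estimated correlation. In the MSP list ssp-16, a small MSP-domain gene, fell by 1.98 ± 0.10. Of 26 other sperm genes 24 fell and 2 did not pass, with the same counts adjusted over the list alone (median -0.82, camera adjusted p = 5.9e-08), and gsp-3, which encodes a sperm phosphatase, fell by 1.65 ± 0.11. The cell cycle again fell, with 41 of 49 genes down, 2 up and 6 not passing, or 2 up and 42 down adjusted over the list alone (median -0.48, camera adjusted p = 5.9e-08). Oocyte and germ line genes fell in 34 of 44 cases, with 2 up and 8 not passing, or 2 up and 36 down adjusted over the list alone (median -0.40, camera adjusted p = 2.2e-06), with adjusted p = 0.0526 with an estimated correlation, and csr-1 fell by 0.97. Intestinal genes rose in 24 of 28 cases and 4 did not pass, or 25 rose and 1 fell adjusted over the list alone (median 0.53, camera adjusted p = 3.0e-07), with 1.12 ± 0.05 for the cathepsin B-like gene cpr-1. Antimicrobial peptide genes rose in 20 of 32 cases, 2 fell and 10 did not pass, with the same counts adjusted over the list alone (median 0.50, camera adjusted p = 1.6e-05), with adjusted p = 0.129 with an estimated correlation, and cnc-7 rose by 2.02 ± 0.08.

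Among single genes at this dose the lipase-like gene lipl-1 rose from 2.40 ± 0.06 to 5.61 ± 0.33 (SD, n = 3, adjusted p = 1.3e-13). The lysozyme genes ilys-3 and lys-10 rose by 3.20 ± 0.10 and 2.89 ± 0.10, mtl-2, which encodes a metallothionein, rose by 2.37 ± 0.09, and the long noncoding RNA tts-1 rose by 2.26 ± 0.07. The largest falls were those of dod-3, a gene regulated by DAF-16, from 7.90 ± 0.09 to 4.60 ± 0.44 (SD, n = 3, adjusted p = 5.6e-14) and of the lysozyme gene lys-3, which fell by 2.51 ± 0.15. In each of these genes all 3 treated arrays lay beyond all 3 control arrays. The yolk protein gene vit-1 rose by 0.48 ± 0.09 (adjusted p = 0.00012) and vit-6 rose by 0.15 (adjusted p = 0.012, or 0.00067 to 0.0952 over 13 alternatives, with the call lost without control 1 and with the arrays of the comparison alone), while vit-2, vit-4 and vit-5 did not pass (0.13, 0.09 and 0.01). Across all genes limma called 6756 probe sets, 3106 up and 3650 down, of which 236 and 243 changed at least 2-fold. With median-centred arrays 3526 were up and 3119 down, so the excess of falls depended on the scaling.

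The third comparison asked what differed between 2.0 and 0.2 mM HF at 3 days. All 33 MSP genes were lower at 2.0 mM, also adjusted over the list alone (median -1.79), and of 26 other sperm genes 19 were lower, 2 higher and 5 did not pass, with the same counts adjusted over the list alone (median -1.71). MSP transcripts had thus risen at the lower dose and fallen at the higher one. Of 77 collagen genes 25 were lower, 4 higher and 48 did not pass, or 5 higher and 28 lower adjusted over the list alone (median -0.13). The largest falls from 0.2 to 2.0 mM were those of dod-3 (-4.31 ± 0.14, adjusted p = 1.9e-16) and lys-3 (-3.92 ± 0.15), and the largest rises those of nspe-1 (3.89 ± 0.14, adjusted p = 3.6e-16) and lipl-1 (3.16 ± 0.15). The difference between doses was called for 2332 probe sets, 1483 up and 849 down, of which 52 and 311 were at least 2-fold. Of the probe sets called against the shared control at both doses, 5155 had the same direction (2149 up and 3006 down, against 808 and 1200.0 for independent lists) and 346 had opposite directions. Simulations with a shared control and no effect gave 0 such probe sets, but hardly any probe set is called where there is no effect. This 0 is thus no measure of the overlap that a shared control brings, and part of the excess may come from the shared control. Across probe sets the changes at both doses had r = 0.651 and covariance 0.148, against 0.493 and 0.00755 in these 20 simulations, a difference in covariance of 0.141.

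The fourth comparison asked how 11-day-old worms kept with 0.2 mM HF differed from untreated 11-day-old worms. MSP genes rose in 22 of 33 cases and 11 did not pass, with 22 also adjusted over the list alone (median 0.72, camera adjusted p = 3.3e-20), with 1.02 ± 0.13 (SE, n = 3 per group) for msp-45. In the 11-day controls msp-45 lay at 4.29, under log2 5. Of 26 other sperm genes 0 rose and 0 fell (median 0.05). Body wall muscle genes rose in 4 of 32 cases, or in 2 with the arrays of the comparison alone, and 28 did not pass, or 7 rose adjusted over the list alone (median 0.08, camera adjusted p = 0.0012), with 0.55 ± 0.06 for tnt-2, which encodes a troponin T, and 0.15 for pat-10, which did not pass. Of 31 genes of moulting and of hedgehog-like proteins 5 rose and 26 did not pass, or 7 rose adjusted over the list alone (median 0.16, camera adjusted p = 3.2e-04), with adjusted p = 0.0653 with an estimated correlation, and noah-2 rose by 0.58 while ptr-2 at 0.05 did not pass. Lysozyme genes fell more than they rose, with 4 of 13 down, 1 up and 8 not passing, or 2 up and 5 down adjusted over the list alone (median -0.11, camera adjusted p = 0.0058), with adjusted p = 0.0976 with an estimated correlation, and ilys-3 fell by 0.93 ± 0.10 while lys-1 at -0.07 did not pass. Cytochrome P450 genes, which oxidise foreign compounds and fatty acids, fell in 5 of 27 cases, with 1 up and 21 not passing, or 3 up and 5 down adjusted over the list alone (median -0.07, camera adjusted p = 0.0239). The list had adjusted p = 0.155 with an estimated correlation. The call of this list was lost without replicate 1 of each group (0.0558) or replicate 3 (0.0703), and over 7 alternatives its adjusted p ran from 0.0201 to 0.155. In it cyp-35A2 fell by 0.59 ± 0.07, cyp-34A8 rose by 0.88 ± 0.11 and cyp-31A5 at -0.07 did not pass.

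Transthyretin-related genes rose at this dose in 4 of 32 cases and 28 did not pass, or 9 rose adjusted over the list alone (median 0.09, camera adjusted p = 0.0016), with adjusted p = 0.265 with an estimated correlation, and ttr-37 rose by 0.88 while ttr-15 at 0.02 did not pass. E02C12.6 rose from 4.68 ± 0.10 to 7.63 ± 0.08 (SD, n = 3, adjusted p = 1.5e-14), the short-chain dehydrogenase gene dhs-14 rose by 1.63 ± 0.11 and the lipase gene fil-2 rose by 1.34 ± 0.08. T10B5.8 fell from 6.68 ± 0.26 to 4.01 ± 0.13 (SD, n = 3, adjusted p = 5.9e-13) and dhs-26 fell by 1.98 ± 0.10. In each of these genes all 3 treated arrays lay beyond all 3 control arrays. The 5 yolk protein genes did not pass (vit-1 0.19, vit-2 0.20, vit-4 0.05, vit-5 0.06, vit-6 0.08). Altogether limma called 444 probe sets, 357 up and 87 down, of which 12 and 2 changed at least 2-fold, and 286 without treated array 3. With median-centred arrays 265 were up and 140 down, and after quantile normalization 340 and 160.

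The fifth comparison asked how 11-day-old worms kept with 2.0 mM HF differed from untreated 11-day-old worms. Transcripts of the germ line rose. Of 44 oocyte and germ line genes 26 rose and 18 did not pass, or 29 rose adjusted over the list alone (median 0.30, camera adjusted p = 2.4e-10), with 0.75 ± 0.07 for lin-41, which acts in oocytes, and 0.61 ± 0.07 for the Notch receptor gene glp-1. MSP genes rose in 23 of 33 cases, 1 fell and 9 did not pass, with the same counts adjusted over the list alone (median 0.92, camera adjusted p = 5.3e-13). Camera gave adjusted p = 0.115 with an estimated correlation. Of 26 other sperm genes only 7 rose and 19 did not pass, also adjusted over the list alone (median 0.15, camera adjusted p = 0.0103, or 0.129 with an estimated correlation), and 4 rose and 1 fell with the arrays of the comparison alone. Cuticle collagen genes rose in 31 of 77 cases and 46 did not pass, or 32 rose and 1 fell adjusted over the list alone (median 0.16, camera adjusted p = 2.4e-09), with adjusted p = 0.0754 with an estimated correlation, and col-98 rose by 0.87 while sqt-3 at 0.15 did not pass. F-box genes fell in 33 of 99 cases, or in 20 with the arrays of the comparison alone, 1 rose and 65 did not pass, or 1 rose and 39 fell adjusted over the list alone (median -0.19, camera adjusted p = 9.9e-05). It had adjusted p = 0.196 with an estimated correlation. Transthyretin-related genes fell in 15 of 32 cases, 1 rose and 16 did not pass, or 1 rose and 17 fell adjusted over the list alone (median -0.21, camera adjusted p = 3.2e-04). Camera gave adjusted p = 0.198 with an estimated correlation. Genes regulated by DAF-16, the transcription factor of the insulin pathway, fell in 7 of 20 cases, 1 rose and 12 did not pass, or 1 rose and 8 fell adjusted over the list alone (median -0.19, camera adjusted p = 0.0078). The list had adjusted p = 0.195 with an estimated correlation. Among these ins-7, an insulin-like gene, fell by 1.08 ± 0.11 and dod-19 fell by 0.88 ± 0.07. Here and below this list does not separate genes that DAF-16 raises from genes that it lowers. Its direction is thus no measure of DAF-16 activity.

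As at 0.2 mM, E02C12.6 rose and T10B5.8 fell at 11 days with 2.0 mM, by 2.62 ± 0.10 (adjusted p = 5.9e-14) and by -1.77 ± 0.12 (adjusted p = 4.3e-10). The lectin-like gene clec-60 rose by 2.06 ± 0.17 (6.78 ± 0.07 against 4.72 ± 0.09, SD, n = 3), the carbonic anhydrase gene cah-4 rose by 1.68 ± 0.09 and the lysozyme gene ilys-2 rose by 1.57 ± 0.15. The glutathione S-transferase gene gst-19 fell by 1.77 ± 0.09 (adjusted p = 3.5e-12) and semo-1 fell by 1.66. In each of these genes all 3 treated arrays lay beyond all 3 control arrays. Of the yolk protein genes vit-1 rose by 0.90 ± 0.09 (adjusted p = 4.8e-07), while vit-4, vit-5 and vit-6 at 0.09, 0.09 and 0.03 and vit-2 did not pass. The limma fit called 3140 probe sets, 1492 up and 1648 down, of which 46 and 34 changed at least 2-fold. The balance turned to 1694 up and 1673 down after quantile normalization and to 1164 up and 1079 down with the arrays of the comparison alone.

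The sixth comparison asked what differed between 2.0 and 0.2 mM HF at 11 days. Oocyte and germ line genes were higher at 2.0 mM in 27 of 44 cases and 17 did not pass, or 28 adjusted over the list alone (median 0.28). Transthyretin-related genes were lower in 23 of 32 cases, 1 was higher and 8 did not pass, or 1 up and 24 down adjusted over the list alone (median -0.34). Genes of C-type lectin-like proteins were lower in 20 of 51 cases, 3 were higher and 28 did not pass, or 3 up and 22 down adjusted over the list alone (median -0.17). The largest rise was that of dhs-26 (2.28 ± 0.10, adjusted p = 2.2e-12), which had fallen at 0.2 mM. The saposin-like gene spp-12 was higher by 1.85 ± 0.10 and ilys-3 by 1.69 ± 0.10 (adjusted p = 1.2e-10), and clc-32 was lower (-1.88 ± 0.16). The difference between doses was called for 3384 probe sets, 1351 up and 2033 down, of which 14 and 80 were at least 2-fold, but 1848 were up and 1818 down after quantile normalization. Against the shared control 145 probe sets had the same direction at both doses (99 up and 46 down, against 48.0 and 12.9 for independent lists) and 122 had opposite directions. The 0 in 20 simulations with no effect is no measure of this, and part of the excess may come from the shared control. Across probe sets r was 0.233 and the covariance 0.011, against 0.498 and 0.00764 in the simulations, a difference in covariance of 0.00337.

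The seventh comparison asked how 3-day-old worms kept with 0.2 mM HF-HQ differed from the untreated worms of that experiment. Lysozyme genes rose in 6 of 13 cases and 7 did not pass, with 6 also adjusted over the list alone (median 0.23, camera adjusted p = 3.2e-04). Among them lys-10 rose from 3.36 ± 0.06 to 7.79 ± 0.18 (SD, n = 3, adjusted p = 2.1e-18) and ilys-2 rose by 2.73 ± 0.15 (SE, n = 3 per group), while ilys-5 at -0.03 did not pass. MSP genes rose in 24 of 33 cases and 9 did not pass, with 24 also adjusted over the list alone (median 0.88, camera adjusted p = 6.7e-11). It had adjusted p = 0.152 with an estimated correlation. Of 26 other sperm genes 5 rose, 1 fell and the rest did not pass (median 0.02). Antimicrobial peptide genes rose in 12 of 32 cases and 20 did not pass, with 12 also adjusted over the list alone (median 0.18, camera adjusted p = 9.7e-04), with adjusted p = 0.211 with an estimated correlation, and abf-5 rose by 0.81 while spp-1 at 0.06 did not pass. Transthyretin-related genes rose in 14 of 32 cases and 18 did not pass, or 16 rose adjusted over the list alone (median 0.25, camera adjusted p = 4.3e-04). The list had adjusted p = 0.205 with an estimated correlation. Oocyte and germ line genes fell in 15 of 44 cases, 2 rose and 27 did not pass, or 2 rose and 18 fell adjusted over the list alone (median -0.13, camera adjusted p = 8.8e-06), with adjusted p = 0.067 with an estimated correlation, and fbf-1, which encodes an RNA-binding PUF protein, fell by 0.90 ± 0.16 while pos-1 at -0.11 did not pass. Cell cycle genes fell in 15 of 49 cases, 1 rose and 33 did not pass, with the same counts adjusted over the list alone (median -0.08, camera adjusted p = 1.7e-04), with adjusted p = 0.102 with an estimated correlation, and cye-1, which encodes cyclin E, fell by 1.35 while rnr-2 at -0.07 did not pass.

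Among single genes at 0.2 mM HF-HQ the collagen gene col-129 rose by 2.74 ± 0.09 (7.91 ± 0.13 against 5.16 ± 0.11, SD, n = 3). The largest falls were those of dpt-1 (4.52 ± 1.28 against 8.27 ± 0.09, SD, n = 3, adjusted p = 6.5e-07), tlf-1 (-3.51 ± 0.56), B0019.2 (-3.20 ± 0.34) and btbd-10 (-2.98 ± 0.58). Other probe sets of tlf-1 and btbd-10 reached only -0.47 and -0.65. Beside these falls, the 5′ minus 3′ signal of ubiquitin was -2.44 ± 0.17 at 0.2 mM, -2.08 ± 0.05 in the controls and -2.15 ± 0.09 at 2.0 mM (SD, n = 3). The yolk protein genes vit-4, vit-5 and vit-6 fell by 0.19, 0.18 and 0.14 (adjusted p = 0.0064, 0.023 and 0.036), while vit-1 at -0.16 and vit-2 at -0.06 did not pass. As a whole, limma called 3353 probe sets, 1761 up and 1592 down, of which 45 and 188 changed at least 2-fold. With median-centred arrays 2600 were up and 1429 down, but without treated array 2 the balance turned to 902 up and 1052 down. The 188 falls of at least 2-fold became 84 without treated array 2 and 327 without treated array 1. When the 6 arrays of this comparison were fitted alone, 376 probe sets were called, 197 up and 179 down, and without treated array 2 the count was 1954. In that fit 17 MSP, 5 lysozyme, 3 antimicrobial peptide and 2 transthyretin-related genes rose and 1 oocyte gene fell, and the 15 falls of cell cycle genes were all lost. There lys-10, ilys-2, col-129, dpt-1 and B0019.2 kept their calls, while fbf-1, cye-1, tlf-1, btbd-10, vit-4, vit-5 and vit-6 lost them. The adjusted p of dpt-1 given above rests on a variance over all arrays, although its SD was 1.28 with treatment and 0.09 in the controls. That value thus does not show by what margin its call held in the fit of these arrays alone.

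**Figure D2:**
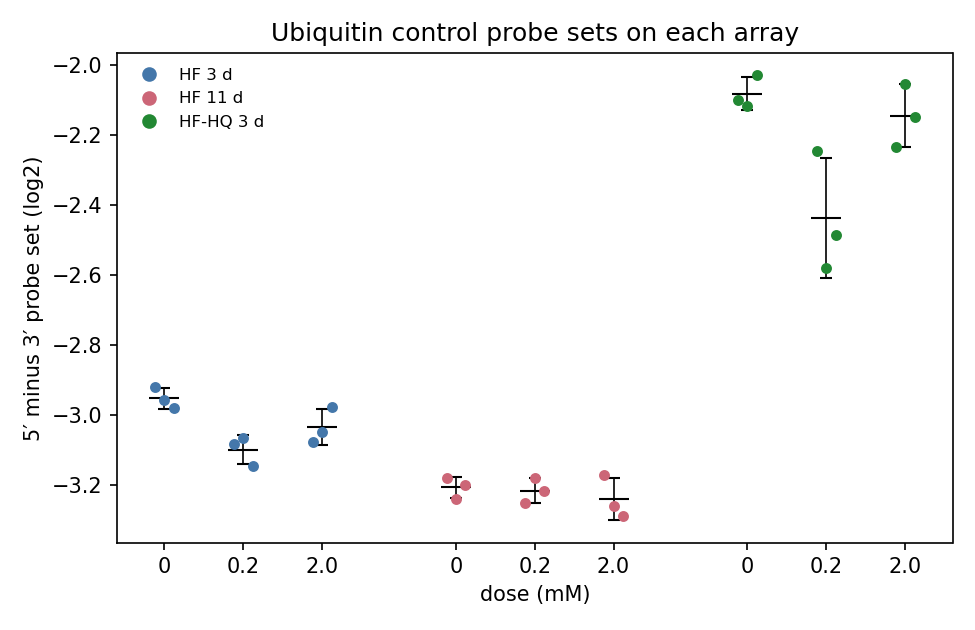
Signal of the 5′ minus that of the 3′ ubiquitin control probe sets (vertical axis, log2) by dose and experiment (horizontal axis, mM), with points for arrays and bars for mean and SD, n = 3 arrays per group. The 5′ minus 3′ value was -2.44 with 0.2 mM HF-HQ and -2.08 in its controls.

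The eighth comparison asked how 3-day-old worms kept with 2.0 mM HF-HQ differed from the same untreated worms. Lysozyme genes, which digest bacterial cell walls, rose in 9 of 13 cases, 1 fell and 3 did not pass, or 10 rose and 1 fell adjusted over the list alone (median 0.96, camera adjusted p = 5.4e-11). Among them lys-10 rose from 3.36 ± 0.06 to 11.26 ± 0.14 (SD, n = 3, adjusted p = 8.8e-24), ilys-3 rose from 3.16 ± 0.08 to 10.21 ± 0.09 (adjusted p = 6.5e-23) and ilys-2 rose by 5.63 ± 0.15. The control values of lys-10, ilys-3, clec-60, Y65B4BR.1 and C50F7.5 lay under log2 5, so the size of their rises depends on how GCRMA sets values near background. Cuticle collagen genes fell in 37 of 77 cases, 3 rose and 37 did not pass, or 3 rose and 45 fell adjusted over the list alone (median -0.24, camera adjusted p = 4.3e-14), and col-98 fell by 1.46 ± 0.10. Intestinal genes rose in 19 of 28 cases, 2 fell and 7 did not pass, or 22 rose and 3 fell adjusted over the list alone (median 0.45, camera adjusted p = 3.5e-09), with 1.31 ± 0.06 for the cathepsin B-like gene cpr-4. Genes regulated by DAF-16 rose in 10 of 20 cases, 2 fell and 8 did not pass, with the same counts adjusted over the list alone (median 0.27, camera adjusted p = 2.5e-05), and the metallothionein gene mtl-1 rose by 3.85 ± 0.18 and fat-7, which encodes a stearoyl-CoA desaturase, by 2.55 ± 0.10. Neuronal genes rose in 21 of 42 cases, 2 fell and 19 did not pass, or 22 rose and 2 fell adjusted over the list alone (median 0.34, camera adjusted p = 9.9e-05), with 0.75 ± 0.08 for the neuropeptide gene flp-5. Antimicrobial peptide genes rose in 15 of 32 cases, 6 fell and 11 did not pass, or 17 rose and 6 fell adjusted over the list alone (median 0.19, camera adjusted p = 1.7e-04), with adjusted p = 0.173 with an estimated correlation, and spp-18 rose by 1.76.

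The lectin-like gene clec-60 rose at 2.0 mM HF-HQ from 2.07 ± 0.01 to 9.55 ± 0.03 (SD, n = 3, adjusted p = 2.6e-19), and Y65B4BR.1 and C50F7.5 rose by 6.80 and 6.51. The largest falls were those of the ribosomal RNA gene rrn-3.1 (8.20 ± 1.21 against 13.09 ± 1.42, SD, n = 3, adjusted p = 3.1e-07), of ule-3 (-3.28 ± 0.36, but 0.01 in its other probe set), of ugt-63, which encodes a UDP-glucuronosyltransferase (-3.02 ± 0.12), of the cystathionine gamma-lyase gene cth-1 (-2.16 ± 0.07, adjusted p = 3.0e-16) and of gpdh-1, which encodes a glycerol-3-phosphate dehydrogenase (-2.13 ± 0.18). In each of these genes all 3 treated arrays lay beyond all 3 control arrays. Of the yolk protein genes vit-1 fell by 0.61 ± 0.09 (adjusted p = 2.3e-05), while vit-2, vit-4, vit-5 and vit-6 did not pass (0.05, -0.08, -0.12 and 0.01). Of the tested probe sets limma called 2608 probe sets, 1464 up and 1144 down, of which 287 and 77 changed at least 2-fold. Without the filter, which tests more probe sets near the floor, 1833 were up and 6731 down.

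**Figure D3:**
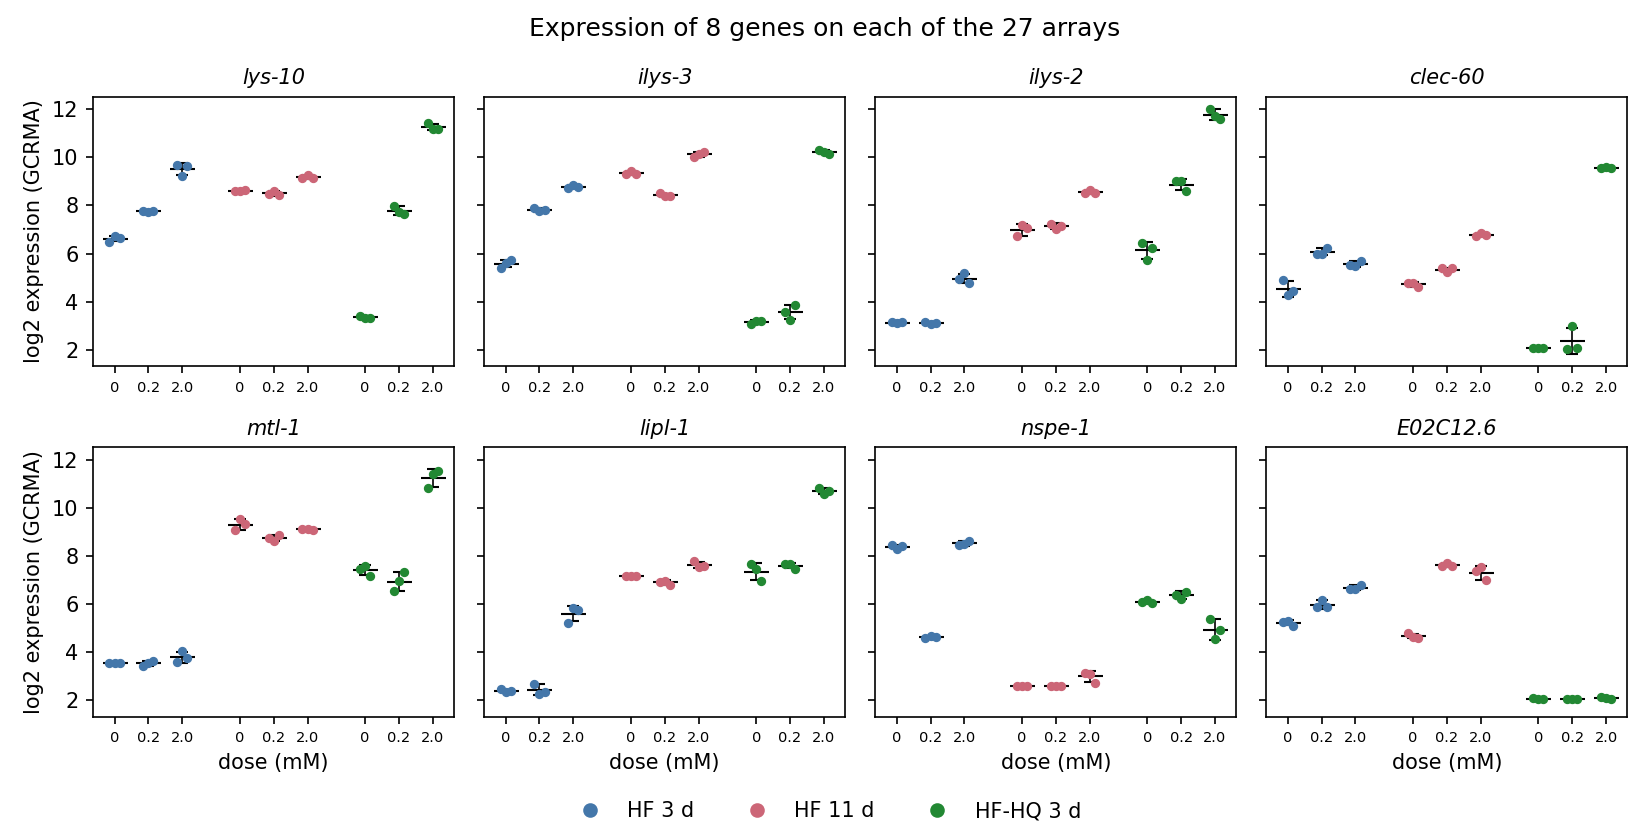
Level of 8 genes (vertical axis, log2) by dose and experiment (horizontal axis, mM), with points for arrays and bars for mean and SD, n = 3 arrays per group. With 2.0 mM HF-HQ lys-10 reached 11.26 and clec-60 reached 9.55, against 3.36 and 2.07 in the controls.

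The ninth comparison asked what differed between 2.0 and 0.2 mM HF-HQ. Collagen genes were lower at 2.0 mM in 51 of 77 cases, 2 were higher and 24 did not pass, or 2 up and 55 down adjusted over the list alone (median -0.39). MSP genes were lower in 23 of 33 cases and 10 did not pass, with 23 also adjusted over the list alone (median -1.03). Lysozyme genes were higher in 9 of 13 cases, 2 were lower and 2 did not pass, or 10 up and 2 down adjusted over the list alone (median 0.65). Intestinal genes were higher in 17 of 28 cases, 3 were lower and 8 did not pass, or 19 up and 3 down adjusted over the list alone (median 0.34). Genes of the unfolded protein response of the endoplasmic reticulum were higher in 11 of 19 cases, 1 was lower and 7 did not pass, with the same counts adjusted over the list alone (median 0.28), but 2 were higher with the arrays of these groups alone. The largest differences were those of clec-60 (7.18 ± 0.17), Y65B4BR.1 (6.82 ± 0.10) and ilys-3 (6.64 ± 0.10) upwards and of rrn-3.1 (-3.61 ± 0.55), ugt-63 (-3.08 ± 0.12) and col-129 (-2.79 ± 0.09) downwards. The difference between doses was called for 3686 probe sets, 1948 up and 1738 down, of which 353 and 166 were at least 2-fold, and for 1523 with the arrays of these groups alone. This balance turned to 1775 up and 2238 down with median-centred arrays and to 1696 up and 2002 down after quantile normalization. Against the shared control 1092 probe sets had the same direction at both doses (695 up and 397 down, against 232 and 164 for independent lists) and 172 had opposite directions. The 0 in 20 simulations with no effect is no measure of this either, and again part of the excess may come from the shared control. Across probe sets r was 0.316 and the covariance 0.0501, against 0.495 and 0.00765 in the simulations, a difference in covariance of 0.0424.

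The tenth comparison asked how untreated 11-day-old worms differed from untreated 3-day-old worms of the HF experiments. The 2 ages appear to have been normalized apart, and the median of all tested probe sets lay -0.24 lower at 11 days, against 0.04 after quantile normalization, so that values after quantile normalization stand beside the deposited ones. All 33 MSP genes fell, also adjusted over the list alone (median -5.54, quantile -5.07, camera adjusted p = 3.8e-13). It had adjusted p = 0.0595 with an estimated correlation. Cuticle collagen genes fell in 66 of 77 cases, 8 rose and 3 did not pass, with the same counts adjusted over the list alone (median -2.32, quantile -2.30, camera adjusted p = 6.7e-10). Other sperm genes fell in 23 of 26 cases and 3 rose, with the same counts adjusted over the list alone (median -2.89, quantile -3.30, camera adjusted p = 8.0e-05). Cytochrome P450 genes rose in 18 of 27 cases, 6 fell and 3 did not pass, with the same counts adjusted over the list alone (median 1.04, quantile 1.49, camera adjusted p = 1.2e-05), and cyp-14A3 rose by 6.09 (quantile 6.85). Genes of oxidative phosphorylation fell in 38 of 43 cases, 2 rose and 3 did not pass, or 2 rose and 39 fell adjusted over the list alone (median -0.71, quantile -0.27, camera adjusted p = 1.0e-04). Ribosomal protein genes fell in 74 of 75 cases, also adjusted over the list alone (median -0.62, camera adjusted p = 7.1e-09), but after quantile normalization 26 rose and 20 fell (median 0.04), so their direction depended on the scaling.

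The largest single changes with age were rises of abf-2, an antibacterial peptide gene (from 2.90 ± 0.01 to 10.88 ± 0.02, SD, n = 3, log2 change 7.98, quantile 8.78, adjusted p = 7.1e-27) and of the chitinase gene cht-1 (7.94, quantile 8.70). The largest falls were those of the lectin-like gene clec-70 (-7.90, quantile -8.30) and of the collagen gene col-139 (-7.33, quantile -7.04). All 5 yolk protein genes fell on the deposited scale (vit-1 -2.63, vit-2 -1.27, vit-4 -0.69, vit-5 -0.54, vit-6 -0.73), but after quantile normalization vit-4 and vit-5 stood at 0.04 and 0.17, so the direction of these depended on the scaling. In all, limma called 8780 probe sets, 3096 up and 5684 down, of which 1088 and 1921 changed at least 2-fold, and this balance turned to 4516 up and 3970 down after quantile normalization and to 8538 up and 7867 down without the filter. The 5′ minus 3′ signal of ubiquitin was -3.21 ± 0.03 at 11 days and -2.95 ± 0.03 at 3 days (SD, n = 3). Age lay together with experiment, so the labels do not separate age from the time of culture and hybridization.

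The eleventh comparison asked whether the response to HF at 11 days differed from that at 3 days, where age again lay together with experiment. At 0.2 mM cell cycle genes responded more upwards at 11 days in 39 of 49 cases and 10 did not pass, or 39 up and 1 down adjusted over the list alone (median 0.43). Oocyte and germ line genes did so in 31 of 44 cases and 13 did not pass, or 32 adjusted over the list alone (median 0.43). At 11 days itself 0 cell cycle genes rose and 0 fell (median -0.03). Of the oocyte and germ line genes 1 rose and 0 fell there (median 0.03). Both differences thus reflected the falls at 3 days. Lysozyme genes responded more downwards in 10 of 13 cases, with 1 upwards and 2 not passing, and with the same counts adjusted over the list alone (median -0.46). Intestinal genes responded more downwards in 17 of 28 cases, with 1 upwards and 10 not passing, or 1 up and 18 down adjusted over the list alone (median -0.38). At 11 days itself 4 intestinal genes rose and 1 fell (median 0.08), against 23 and 0 at 3 days (median 0.37). At 2.0 mM MSP genes responded more upwards in 32 of 33 cases and 1 downwards, with the same counts adjusted over the list alone (median 2.07), and other sperm genes in 25 of 26 cases, also adjusted over the list alone (median 0.93). Oocyte and germ line genes did so in 39 of 44 cases, with 2 downwards and 3 not passing, or 40 up and 2 down adjusted over the list alone (median 0.70). The medians at 11 and 3 days were 0.92 and -1.13 for MSP genes and 0.15 and -0.82 for other sperm genes. In the 11-day controls msp-45, msp-64 and msp-3 lay at 4.29, 5.04 and 5.41. Falls of such genes could therefore not show in full at 11 days. The difference between ages was called for 4739 probe sets at 0.2 mM, 2901 up and 1838 down, and for 6884 at 2.0 mM, 3635 up and 3249 down. With median-centred arrays both balances turned, to 1951 up and 2615 down at 0.2 mM and to 3041 up and 3811 down at 2.0 mM.

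The twelfth comparison asked whether HF-HQ and HF acted differently at the same dose, each against the control of its own experiment. Preparation lay together with experiment, so the labels do not separate a difference between preparations from one between experiments, whose untreated worms differed as well. At 2.0 mM lysozyme genes responded more upwards to HF-HQ in 10 of 13 cases, with 1 downwards and 2 not passing, and with the same counts adjusted over the list alone (median 1.35, camera adjusted p = 7.8e-06). MSP genes did so in 32 of 33 cases and 1 did not pass, or 33 adjusted over the list alone (median 1.02, camera adjusted p = 3.0e-10). Camera gave adjusted p = 0.151 with an estimated correlation. With HF-HQ itself 1 MSP gene rose and 1 fell (median -0.07), so the difference reflected the falls with HF (median -1.13). In the HF-HQ controls msp-74 and msp-50 lay at 4.07 and 4.09, against 10.35 and 11.03 in the HF controls. Falls of such genes could therefore not show in full with HF-HQ. UDP-glucuronosyltransferase genes responded more downwards to HF-HQ in 25 of 37 cases, with 2 upwards and 10 not passing, or 2 up and 26 down adjusted over the list alone (median -0.64, camera adjusted p = 3.2e-07). The list had adjusted p = 0.0563 with an estimated correlation. Collagen genes responded more downwards in 38 of 77 cases, with 6 upwards and 33 not passing, or 6 up and 41 down adjusted over the list alone (median -0.35, camera adjusted p = 1.5e-06). It had adjusted p = 0.129 with an estimated correlation. Body wall muscle genes responded more downwards in 19 of 32 cases, with 2 upwards and 11 not passing, or 2 up and 21 down adjusted over the list alone (median -0.48, camera adjusted p = 5.9e-05). With HF-HQ itself 3 muscle genes rose and 5 fell (median -0.04), and with HF 18 rose and 3 fell (median 0.28). At 0.2 mM genes of the glyoxylate cycle and gluconeogenesis responded more downwards to HF-HQ in 10 of 14 cases and 4 did not pass, with 10 also adjusted over the list alone (median -0.31, camera adjusted p = 4.2e-05). With HF-HQ itself 1 of these genes rose and 2 fell (median -0.01), and with HF 10 rose and 0 fell (median 0.32). Cell cycle genes responded more upwards at that dose in 32 of 49 cases, with 1 downwards and 16 not passing, or 36 up and 1 down adjusted over the list alone (median 0.35, camera adjusted p = 5.9e-05). Camera gave adjusted p = 0.0731 with an estimated correlation. With HF-HQ itself 1 cell cycle gene rose and 15 fell (median -0.08), against 1 and 41 with HF (median -0.45), so the falls were smaller with HF-HQ. The difference was called for 4467 probe sets at 0.2 mM, 2710 up and 1757 down, and for 5352 at 2.0 mM, 3063 up and 2289 down. At 2.0 mM this balance turned to 2620 up and 2686 down with median-centred arrays and to 3123 up and 3621 down without the filter.

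The last comparison asked how the untreated 3-day-old worms of the HF-HQ experiment differed from those of the HF experiment, which had the same age and dose. The median of all tested probe sets lay 1.65 higher in the HF-HQ experiment, against 0.05 after quantile normalization, and 10730 probe sets were called, 9980 up and 750 down, against 4831 up and 4395 down after quantile normalization and 3914 up and 5393 down with median-centred arrays. The 5′ minus 3′ signal of ubiquitin was -2.08 ± 0.05 in the HF-HQ experiment and -2.95 ± 0.03 in the HF experiment (SD, n = 3), and the cause of this was not tested. MSP genes were lower in 32 of 33 cases (median -3.52) and in all 33 after quantile normalization (median -4.93). Other sperm genes were lower in 18 of 26 cases and higher in 8 (median -2.53), and lower in 21 and higher in 3 after quantile normalization (median -3.46). Genes first expressed in the embryo were higher in 23 of 25 cases and lower in 2 (median 3.69), and higher in 17 and lower in 3 after quantile normalization (median 2.50). Among single genes the largest differences were those of pud-3 (7.44, quantile 6.14) and cht-1 (7.42, quantile 6.09) upwards and of clec-70 (-8.35, quantile -8.60) and msp-50 (-6.94, quantile -7.69) downwards.

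**Figure D4:**
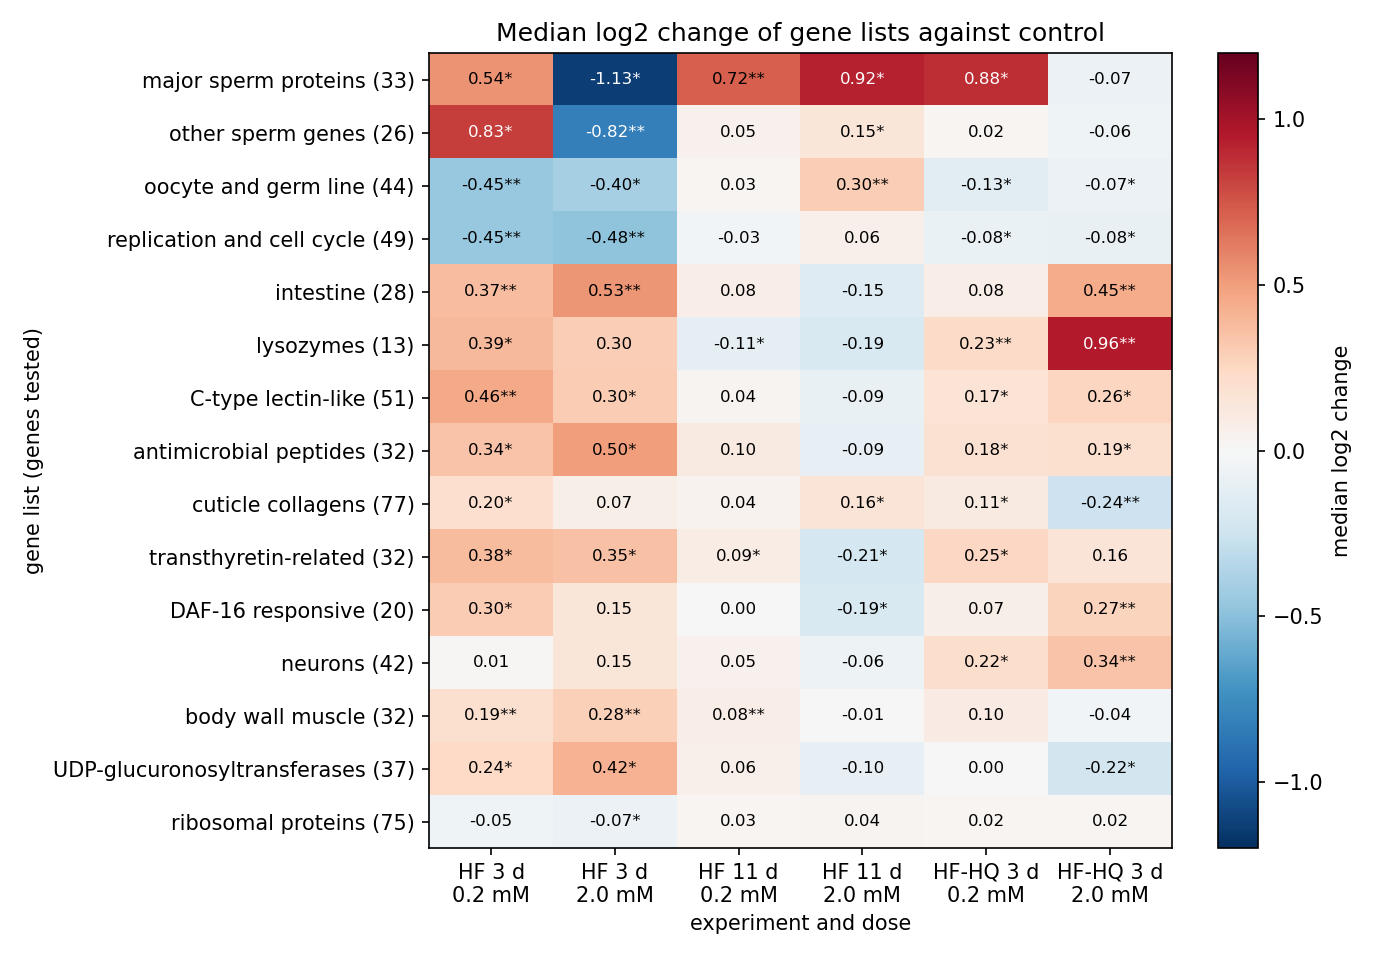
Median log2 change of the tested genes of selected lists (colour and number, log2) in the 6 comparisons of treated with untreated worms (columns), n = 3 arrays per group, with 1 asterisk where camera called the list and a pair where it did so with an estimated correlation as well. Lysozymes had a median of 0.96 with 2.0 mM HF-HQ and MSP genes had -1.13 at 3 days with 2.0 mM HF.

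Of the 216 tests of a list against the other genes in the 6 comparisons of treated with untreated worms, camera called 77, of which 19 held with an estimated correlation. With 0.2 mM HF at 3 days these were cell cycle, oocyte and germ line, intestinal, lectin-like, body wall muscle and glyoxylate genes. With 2.0 mM HF at 3 days these were sperm genes other than MSP, cell cycle, intestinal and body wall muscle genes. At 11 days they were MSP and body wall muscle genes with 0.2 mM HF and oocyte and germ line genes with 2.0 mM. With HF-HQ they were lysozymes at 0.2 mM and lysozymes, collagens, intestinal, DAF-16 regulated and neuronal genes at 2.0 mM. Of 36 such tests with age 17 were called and 9 held, and of 72 with the difference between preparations 27 were called and 5 held.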

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

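The tests on other probe sets of the same genes, on leaving out arrays, on ranks and on tissue lists were chosen only after the results were seen. The other splits of the arrays and the comparison with the change with age were planned.

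The first pattern was in 188 probe sets that fell at least 2-fold with 0.2 mM HF-HQ (median -1.32), of which 3 were called lower at 2.0 mM (median -0.13). Other probe sets of the same genes, outside the falls, had a median of -0.17 (159 probe sets of 125 genes, interquartile range -0.41 to -0.03), whereas the like value for falls with 2.0 mM HF at 3 days was -0.88 (29 probe sets). Leaving out probe sets that were themselves among the falls moves both medians towards 0, and probe positions were not used. Signal lost away from the 3′ end may account for part of the falls. The 5′ minus 3′ signal of the ubiquitin control probe sets, which no comparison used, was -2.44 with 0.2 mM HF-HQ against -2.08 in the controls, and the middle minus 3′ signal was -2.08 against -1.52. Without the array with the lowest values, replicate 2, 83 of the 188 stayed called and 2-fold lower, and without replicate 1 there were 327 such falls, which leaves open how much of the pattern that array brought. Lower levels of these genes stayed open too, since 54 of the 159 other probe sets were called lower.

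The second pattern was the lower level of sperm transcripts in the 3-day controls of the HF-HQ experiment than in those of the HF experiment. The median MSP gene stood at rank percentile 60.5 in the former and 96.5 in the latter, a difference of 36.04, which argues against a separate normalization that keeps the order of genes as the whole cause. Sperm genes other than MSP stood at 54.4 against 70.1, a difference of 15.74, which is consistent with fewer sperm in the worms of the HF-HQ experiment. An older age of these worms cannot be told apart from this, since over the 100 probe sets with the largest rises with age they lay 0.489 of the way from the 3-day to the 11-day controls (bootstrap over probe sets 0.36 to 0.60). The bootstrap measures spread between probe sets, which are not independent, and not between arrays. These probe sets were also chosen on the same HF controls that set the ends of the scale.

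The third pattern was that MSP transcripts stood at rank percentile 96.5 in 3-day controls, 97.7 with 0.2 mM HF and 90.6 with 2.0 mM. A smaller share of germ line would by itself raise all other tissues alike. At 2.0 mM, where sperm transcripts fell, neuronal genes stood -0.377 from intestinal ones (medians 0.15 and 0.53, permutation over genes, adjusted p = 0.0021 over 3 pairs at 2 doses). A separate change of intestinal genes would give this as well, and the permutation measures spread between genes, not between arrays. A smaller share of germ line thus stayed open. The other pairs at this dose did not pass, with muscle at 0.13 from neurons and -0.24 from intestine (permutation over genes, adjusted p = 0.290 and 0.0612). A later stage at 2.0 mM cannot be told apart from other causes, since across 11040 probe sets without sperm genes, which are not independent, Spearman's rho of the change between doses with the change with age was 0.0827 (Pearson 0.286). A direct effect of the preparation on sperm transcripts was not tested.

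Responses that differed between ages or preparations were singled out because the difference itself passed the test. Between ages these were 4739 probe sets at 0.2 mM HF and 6884 at 2.0 mM, and between preparations 4467 at 0.2 mM and 5352 at 2.0 mM. In 100 splits of the arrays the highest of the other splits reached 5069, 5517, 5605 and 5230. The splits exchanged treated and untreated arrays within an experiment, which removes the responses themselves. They therefore cannot tell whether 2 responses differed by chance. Splits that gave such counts kept the real grouping of 1 of the 2 experiments, and splits that kept neither gave at most 3 probe sets with limma.

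At 0.2 mM HF the response at 11 days was higher than at 3 days for nspe-1 (3.73 ± 0.19, SE, adjusted p = 7.4e-12 with limma), nspe-7 (3.02), F35A5.2 (2.38), C10C5.3 (2.32) and E02C12.6 (2.196). It was lower for ilys-3 (-3.15, adjusted p = 2.0e-12 with limma), T10B5.8 (-2.65), C40H1.7 (-2.21), fbxa-163 (-2.14) and gst-24 (-2.03). In both 11-day groups nspe-1, nspe-7, F35A5.2 and C10C5.3 lay under log2 5, as did T10B5.8 in both 3-day groups, so falls could not show in full there. At 2.0 mM it was higher at 11 days for msp-3 (2.46), msp-64 (2.44), dod-3 (2.43), msp-45 (2.40) and msp-40 (2.35). It was lower for lipl-1 (-2.75), C40H1.7 (-2.72), tts-1 (-2.46), ZK1290.5 (-2.44) and ilys-3 (-2.43). In the 11-day controls msp-45, msp-64 and msp-3 lay at 4.29, 5.04 and 5.41, so falls of these could not show in full there either.

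The response to 0.2 mM was higher with HF-HQ than with HF for nspe-1 (3.999), lys-10 (3.30, quantile 2.27), F35A5.2 (2.77), ilys-2 (2.74) and C10C5.3 (2.67). It was lower for btbd-10 (-2.57), gtap-1 (-2.57), sup-26 (-2.56), dpt-1 (-2.515) and anc-1 (-2.44), of which the call of btbd-10 was lost with the arrays of these groups alone (adjusted p = 0.105 with limma), and those of btbd-10 and gtap-1 without arrays 2 and 3 at this dose (-0.15 and -0.65). With HF, F35A5.2, ilys-2, sup-26 and btbd-10 lay under log2 5 in both groups, and other probe sets of btbd-10, gtap-1 and anc-1 reached only -0.49, -0.67 and -0.25. At 2.0 mM it was higher with HF-HQ for Y65B4BR.1 (6.73, quantile 5.29), C50F7.5 (6.52, quantile 5.30), clec-60 (6.46, quantile 4.96), lys-10 (5.01, quantile 4.19) and W03F9.4 (4.98, quantile 4.04). It was lower for rrn-3.1 (-4.99), gpdh-1 (-3.73), ule-3 (-3.32, but -0.30 in its other probe set), ugt-63 (-3.13) and F46F2.3 (-2.91). With HF, Y65B4BR.1, C50F7.5, W03F9.4 and gpdh-1 lay under log2 5 in both groups.

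For the other comparisons 10 splits of the arrays were possible, too few for a share under 0.05. With HF at 3 days the real value and the highest other were 6537 and 1 at 0.2 mM, 6756 and 0 at 2.0 mM, and 2332 and 18 between doses. At 11 days these were 444 and 0, 3140 and 2, and 3384 and 1. With HF-HQ these were 3353 and 261, 2608 and 22, and 3686 and 4. For age these were 8780 and 0 and for the controls of both experiments 10730 and 2.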

How the results depend on the processing

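The fit without 2 of the 3 arrays at 0.2 mM HF-HQ was chosen after the data were seen. Most counts stayed within 1.5 times their value under a stricter filter, centring, quantile normalization, a variance trend and a replicate block. Without the filter, which tests more probe sets near the floor, 767 were called at 11 days with 0.2 mM HF, 8564 with 2.0 mM HF-HQ, of which 6731 were down instead of 1144, 16405 with age, 20139 between controls and 227 in the same direction at both doses at 11 days. With only the arrays of the comparison 376 were called with 0.2 mM HF-HQ and 1523 between doses of HF-HQ, but 6704 and 6815 with HF at 3 days and 2231 with 2.0 mM HF-HQ, and the cause was not tested. With pooled controls, whose 2 sets differ in level, 7272 and 6443 were called with 0.2 and 2.0 mM HF-HQ, 6956 and 5935 of them up. Without arrays 2 and 3 at 0.2 mM HF-HQ, where the lone array is taken to vary like the others, 820 were called at that dose and 1607 between doses. Of 77 camera calls 19 were left with an estimated correlation, and fry made 146. Leaving out 1 array gave 286 (without treated array 3) to 375 (without control 3) instead of 444 at 11 days with 0.2 mM HF, and 1954 (without treated array 2) to 4182 (without treated array 1) instead of 3353 with 0.2 mM HF-HQ. After quantile normalization vit-5 and vit-4 reversed with age to 0.174 and 0.0413, as this removes the lower median at 11 days. The balance of rises and falls depended on the scaling in most comparisons, as given beside their counts. Centring turned it with HF at 3 days, between doses of HF-HQ, between ages in response, between controls and between preparations at 2.0 mM, and quantile normalization turned it with age, with 2.0 mM HF at 11 days and between doses at 11 days and of HF-HQ. Of 2214 values of named genes with 1 array left out 1975 stayed past the threshold in the same direction, 29 fell short of it, 208 stayed short of it and 2 passed anew. With only the arrays of the comparison 273 stayed past it, 21 fell short and 35 stayed short. Signal near the background limits what can be said of genes with low values.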

Other observations

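The lists and tests in this part were planned, and which comparison is printed for a list was chosen after the values were seen. More UDP-glucuronosyltransferase genes, whose products couple foreign compounds to sugars, rose than fell at 3 days with 2.0 mM HF. With 2.0 mM HF-HQ more of them fell than rose. Of 37 UDP-glucuronosyltransferase genes 23 rose, 1 fell and 13 did not pass at 3 days with 2.0 mM HF, or 23 rose and 2 fell adjusted over the list alone (median 0.42, camera adjusted p = 4.8e-04). It had adjusted p = 0.195 with an estimated correlation. With 2.0 mM HF-HQ 16 of these genes fell, 3 rose and 18 did not pass, or 3 rose and 17 fell adjusted over the list alone (median -0.22, camera adjusted p = 2.0e-04). This call had adjusted p = 0.166 with an estimated correlation. Of 26 glutathione S-transferase genes 16 rose, 3 fell and 7 did not pass at 3 days with 0.2 mM HF, or 16 rose and 4 fell adjusted over the list alone (median 0.35, camera adjusted p = 0.0022). Here adjusted p = 0.211 with an estimated correlation. Of 24 short-chain dehydrogenase genes 11 rose and 13 did not pass with 0.2 mM HF-HQ, or 12 rose adjusted over the list alone (median 0.17, camera adjusted p = 0.0148). Also here adjusted p = 0.331 with an estimated correlation, and all 11 calls were lost when the arrays of the comparison were fitted alone. Of 22 ABC transporter genes 6 fell, 1 rose and 15 did not pass with 2.0 mM HF-HQ, with the same counts adjusted over the list alone (median -0.10, camera adjusted p = 0.0897).

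More genes of lipid and sugar metabolism rose than fell at 3 days with 0.2 mM HF. There 40 of 77 genes of fatty acid metabolism rose, 12 fell and 25 did not pass, or 40 rose and 13 fell adjusted over the list alone (median 0.20, camera adjusted p = 8.5e-04). The list had adjusted p = 0.102 with an estimated correlation. Of 14 genes of the glyoxylate cycle and gluconeogenesis 10 rose and 4 did not pass, or 11 rose adjusted over the list alone (median 0.32, camera adjusted p = 6.3e-04). Of 17 eggshell genes 13 fell, 2 rose and 2 did not pass, with the same counts adjusted over the list alone (median -0.55, camera adjusted p = 0.0018). For these adjusted p = 0.102 with an estimated correlation. Sperm genes other than MSP split at this dose, with 17 up, 8 down and 1 not passing, also adjusted over the list alone, a median of 0.83 and a mean of 0.21 (camera adjusted p = 0.0301). This had adjusted p = 0.193 with an estimated correlation. Histone genes fell in 7 of 23 cases and rose in 2 at this dose (2 rose and 2 fell adjusted over the list alone, and 2 rose and 4 fell with the arrays of the comparison alone), but rose in 5 and fell in 2 after centring, so their direction depended on the scaling. TGF-beta and dauer genes fell in 7 of 24 cases and rose in 3 (3 rose and 6 fell adjusted over the list alone), but rose in 7 and fell in 5 after centring, so their direction depended on the scaling as well.

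Genes of stress responses were tested as well. With 2.0 mM HF-HQ 5 of 15 heat shock genes rose and 10 did not pass, also adjusted over the list alone, with a median of -0.04 but a mean of 0.26 and a test directed upwards (camera adjusted p = 0.146). Of 24 genes of antioxidant defence 3 rose, 3 fell and 18 did not pass with 2.0 mM HF-HQ, with the same counts adjusted over the list alone (median 0.03, camera adjusted p = 0.812). Of 11 genes of the response to metals 3 rose, 1 fell and 7 did not pass, with the same counts adjusted over the list alone (median 0.13, camera adjusted p = 0.0928). Of 19 genes of the unfolded protein response 7 fell, 1 rose and 11 did not pass with 0.2 mM HF-HQ, with the same counts adjusted over the list alone (median -0.22, camera adjusted p = 0.0025). That list had adjusted p = 0.145 with an estimated correlation, and 1 fall was left when the arrays of the comparison were fitted alone. Of 72 nuclear hormone receptor genes 29 rose, 5 fell and 38 did not pass at 3 days with 2.0 mM HF, with the same counts adjusted over the list alone (median 0.17, camera adjusted p = 0.0124). They had adjusted p = 0.201 with an estimated correlation.

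With age 4 of 6 insulin-like peptide genes rose and 2 did not pass, also adjusted over the list alone (median 1.89, camera adjusted p = 8.1e-04). Of 24 autophagy genes 13 rose, 5 fell and 6 did not pass, with the same counts adjusted over the list alone (median 0.24, camera adjusted p = 0.0103). Of 4 chitinase genes, too few for camera, 3 rose and 1 did not pass, also adjusted over the list alone (median 0.35). At 11 days with 2.0 mM HF 10 of 25 embryonic genes fell, or 4 with the arrays of the comparison alone, and 15 did not pass, with 10 also adjusted over the list alone (median -0.20, camera adjusted p = 0.0292). These had adjusted p = 0.158 with an estimated correlation.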
